A study of Mus musculus with 4 samples.

How the data were processed

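Single-cell 5' gene expression, surface antibody tags and V(D)J contigs had been measured by the authors in sorted reporter-positive spleen cells of 4 mice immunised with ovalbumin. All 4 mice, 2 per genotype, had been pooled in 1 preparation, so each of the 4 GEO samples is a library or lane of the same pool and none is a mouse. No library or lane separates the genotypes. The authors' processing notes name bcl2fastq 2.20.0.422, Cell Ranger 3.1.0 and the builds mm10 and GRCm38. The matrix is deposited as raw UMI counts, 31053 genes by 8116 cells and 57294722 UMIs, with 687 to 44278 UMIs (median 5525.5) and 501 to 5746 genes (median 1799) per cell. The authors' metadata give the total counts and the number of genes of each cell, and mitochondrial UMIs in percent (at most 7.92). They also give, as other values per the file headers, the mouse and genotype of each cell, the cluster, the heavy chain constant gene, the switched status, V mutations per cell and the clone. Totals and numbers of genes recomputed from the matrix were checked against the metadata and were equal in all 8116 cells, and mitochondrial percent was the same to rounding. The authors' cell filters are not stated. All 8116 deposited cells were classed as singlets by their tags. Doublets of 2 cells from the same mouse carry 1 tag and stay in, so cells above 3 times the median UMIs of their class were left out in an alternative.

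The mouse was the unit throughout, and each cell was given to a mouse from the antibody tag named in the metadata. That WT stands for +/ki and KO for -/ki was read from the names. The mice gave 14797151 and 13805708 UMIs (+/ki) and 15423248 and 13268615 UMIs (-/ki). Comparisons, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Fits of single clusters, V mutations, pre-plasmablasts in clones and the alternatives marked as added were chosen after the data were seen. No tdTomato or Cre transcript was in the matrix.

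For gene expression, UMIs were summed per mouse over all cells, germinal centre cells (GC.DZ and GC.LZ), memory cells (Mem.GC, Mem.Act, Mem.Act2) and plasmablasts (PB), with at least 20 cells per mouse. They were tested with the edgeR 4.0.16 quasi-likelihood test (TMM normalisation, filterByExpr) at a Benjamini-Hochberg adjusted p of 0.05. The 2 pre-plasmablast clusters belonged to no class fixed beforehand and were fitted alone. The difference of the genotype effect between plasmablasts and germinal centre cells was tested as an interaction with the mouse as a block. CPM of genes are summed UMIs over the TMM-scaled library size of the fit in question, and CPM of Aicda are summed UMIs over all UMIs. Among passing genes with a mean of at least 10 CPM in 1 genotype and no overlap of the mice, up to 12 per direction were to be named, leaving out variable, diversity and joining segments and predicted genes. Where fewer than 6 passed, the 10 with the smallest p are given as not passing.

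The 24 gene lists were tested with limma 3.58.1 camera on voom values with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The p values were adjusted over 229 pairs of list and class. The lists are switched and unswitched Igh constant genes, plasma cell programme, unfolded protein response and secretion, light zone activation, dark zone, germinal centre identity, memory B cell, S phase, G2 and M phase, repair of AID-induced lesions, p53 targets, apoptosis regulators, interferon response, MYC and ribosome biogenesis, oxidative phosphorylation, MHC class II presentation, homing and adhesion receptors, B cell receptor signalling, immediate early and handling stress, and T cell, myeloid, NK and cytotoxic, and erythroid and platelet markers. With 2 mice per genotype, 0 of the 66 calls made with the preset correlation stayed with an estimated correlation, so list results rest on the preset value.

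The edgeR fits were tested on simulated data with the depth and spread of each class and 100 genes changed by each fold. For the interaction 1 spread per gene served both classes. The common biological coefficient of variation in edgeR was 0.12 in germinal centre cells and 0.38 in plasmablasts. The simulated interaction thus tells nothing about the effect of unequal spread. Of genes changed by a fold of 2, the fit recovered 56% over all cells, 74% in germinal centre cells, 74% in memory cells, 16% in plasmablasts and 2% in the interaction. For a fold of 4 it recovered 98%, 98%, 99%, 89% and 51%. In single clusters the recovery at a fold of 2 and 4 was 59% and 100% (GC.DZ), 63% and 98% (GC.LZ), 54% and 100% (Mem.GC), 70% and 100% (Mem.Act), 56% and 98% (E-prePB) and 5% and 95% (L-prePB). With immunoglobulin genes left out, recovery at a fold of 2 was 88% over all cells, 89% in germinal centre cells, 85% in memory cells and 56% in plasmablasts. Among unchanged genes 16, 21, 18 and 17 false calls were made over all cells, in germinal centre cells, plasmablasts and memory cells (10 in the interaction, 15 in GC.DZ, 10 in GC.LZ, 13 in Mem.GC, 13 in Mem.Act, 4 in E-prePB and 6 in L-prePB), and 7, 14, 6 and 11 with immunoglobulin genes left out. Some fits thus made more false calls than the nominal 5% of their calls. In the data the same fits called 6, 6, 5 and 16 genes, 9 in the interaction, and 5, 20, 23, 13, 1 and 5 in these clusters. The simulated false calls were made beside 100 changed genes per fold. At a set adjusted p false calls grow with the number of calls. The simulated numbers thus do not give how many of the calls in the data are false. On simulated data camera found the raised list every time and called 0 of 19 others. Simulated genes varied independently, so this tells nothing about camera where the genes of a list vary together.

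Shares of clusters and of switched cells are per mouse with 95% exact (Clopper-Pearson) intervals, and genotypes were compared by an exact two-sided permutation test of means, which with 2 against 2 mice cannot go below 0.333. Numbers of cells per cluster were also tested with edgeR. Switched cells are those whose deposited constant gene is Ighg, Igha or Ighe, out of 5555 cells with a call. Of 4348 cells with a call and at least 5 Igh constant UMIs, 97.52% had the same status by UMIs. Clones are those of the metadata, 4084 over 5855 cells, of which 3 occurred in 2 mice. Counts were thinned to 2000 UMIs per cell where depth mattered. Draws to the smallest mouse were repeated 100 times. Gene locations are from GENCODE vM21 on GRCm38, matched by symbol.

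Alternatives tried were RLE size factors, DESeq2 1.42.0, no filter on low counts, immunoglobulin genes left out, cells above 3 times the median left out, thinning, other UMI rules for switching, clones of 3 or more cells, drawing down, a fit with no mouse block, and each mouse left out. Added after the data were seen were 1 cell per clone, robust empirical Bayes, pre-plasmablasts added to plasmablasts, cells with an unswitched call only and each clone counted once per cluster. The last of these used only cells with a clone. DESeq2 was run only with immunoglobulin genes kept, so its calls beside edgeR fits without them differ in tool and in gene set. The library of origin and the totals of antibody tag counts in the metadata were not used, and the tag definitions hold no measurement. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.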

Results

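The deposited matrix held 8116 sorted spleen cells that carried the AID reporter, from 4 immunised mice aged 14 weeks. They came in groups of 2: Aicda +/ki mice, which keep 1 working copy of Aicda, and Aicda -/ki mice, which have none. The +/ki mice are named WT and the -/ki mice KO in the deposited metadata. Every cell had been placed by the authors in 1 of 8 clusters, all of the B lineage. These were dark zone (GC.DZ) and light zone (GC.LZ) germinal centre cells, 3 memory clusters (Mem.GC, Mem.Act, Mem.Act2), early and late pre-plasmablasts (E-prePB, L-prePB) and plasmablasts (PB). The mice gave 2119 and 1936 (+/ki) and 2171 and 1890 (-/ki) cells, with medians of 5163, 5588.5, 5677 and 5539.5 UMIs per cell. All differences are given as -/ki minus +/ki, and errors of means are SDs between the 2 mice of a genotype.

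Aicda, which encodes AID, the deaminase that starts class switching and somatic hypermutation, was read at like levels in both genotypes. The gene lies on chromosome 6 from 122553801 to 122564180 of GRCm38. Over all cells it gave 152 ± 11.2 CPM in +/ki mice and 156 ± 24.8 CPM in -/ki mice (n = 2 mice each; edgeR log2 fold change 0.06, standard error 0.12, adjusted p = 0.920). In germinal centre cells Aicda stood at 260 ± 3.12 and 288 ± 14.6 CPM (log2 0.15, standard error 0.06, adjusted p = 0.547). An Aicda UMI was found in 84.5% and 80.9% of +/ki and 83.3% and 84.1% of -/ki germinal centre cells. In plasmablasts, which do not express Aicda, the background share was 2.90% and 1.75% against 3.23% and 3.77%, at median depths of 16835, 15825, 19370 and 16459 UMIs. Germinal centre cells held medians of 8688, 7374, 7524 and 7308 UMIs. After thinning to 2000 UMIs per cell the germinal centre shares were 43.7%, 41.9%, 43.2% and 42.4%, and the plasmablast shares 1.47%, 0%, 0% and 1.89%. A 5' read outside the disrupted part of Aicda is still counted, so these values check nothing about the genotype.

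Class switching, the step that replaces the IgM constant region, was found almost only in +/ki mice. Among cells with a heavy chain constant call, 17.1% and 25.9% were switched in the 2 +/ki mice (228 of 1335 and 297 of 1146) against 0.121% and 0.350% in the 2 -/ki mice (2 of 1647 and 5 of 1427). The means were 21.5 ± 6.25% and 0.236 ± 0.162% (exact permutation p = 0.333, below which 2 mice against 2 cannot go). Germinal centre cells were the most switched in +/ki mice (39.1 ± 4.07%), while the -/ki mice had 0 of 681 cells (upper limit 0.441%, set at 3 counts) and 0.292% of 685 cells. In +/ki mice GC.DZ held 43.3 ± 8.01%, GC.LZ 34.4 ± 1.02%, Mem.GC 23.7 ± 5.99%, plasmablasts 17.7 ± 1.47%, Mem.Act 6.01 ± 3.35%, L-prePB 5.44 ± 4.09% and E-prePB 5.27 ± 2.36%. The commonest switched isotype was IgG2b, at 7.49% and 11.1% of +/ki cells with a call. IgG1 stood at 3.45% and 7.94%, IgG2c at 4.57% and 3.93%, IgA at 0.899% and 1.57%, and IgG3 at 0.674% and 1.40%. Of the 7 switched calls in -/ki mice, 3 had at least 5 Igh constant UMIs, and 2 of these 3 had mostly switched UMIs. A V mutation was carried by 4 of the 7 cells, against 8.42% and 2.03% of all -/ki cells with a clone. Whether these 7 cells had been given to the right mouse was not tested.

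Somatic hypermutation, read as deposited V mutations per cell, was also far more frequent in +/ki mice. The mean number was 2.14 and 3.14 per cell in the +/ki mice and 0.0989 and 0.0399 in the -/ki mice (2.64 ± 0.707 and 0.0694 ± 0.0418, exact permutation p = 0.333). In germinal centre cells it was 4.37 ± 1.24 against 0.0398 ± 0.0094, and 80.9% and 93.3% of +/ki germinal centre cells were mutated against 4.06% and 1.15%. Over all -/ki cells 8.42% and 2.03% were mutated, and in the first -/ki mouse 15.8% of Mem.GC, 12.9% of plasmablast and 12.2% of E-prePB cells. Plasmablasts carried 2.69 and 1.35 V mutations in +/ki mice against 0.177 and 0.143. Mem.GC cells held 2.10 ± 0.26, E-prePB 1.31 ± 0.15 and Mem.Act 0.944 ± 0.571 V mutations in +/ki mice. Within the +/ki germinal centre, switched cells carried more V mutations (4.02 and 6.45) than unswitched cells (3.20 and 4.24). How V mutations were counted is not stated in the files, and their analysis was added after the metadata had been seen.

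**Figure D1:**
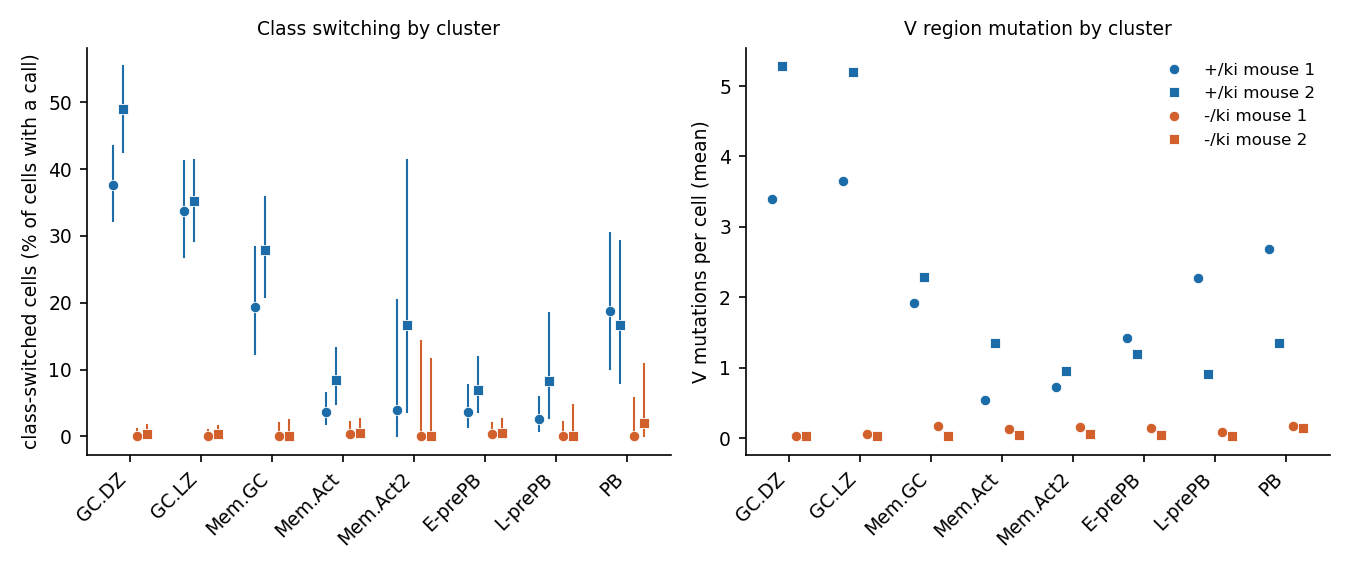
Left, class-switched cells as percent of cells with a constant gene call in each of the authors' clusters, 1 point per mouse with a 95% exact interval; right, mean V mutations per cell, 1 point per mouse. The +/ki mice lie above both -/ki mice for V mutations in every cluster. Their means are 3.40 and 5.28 in GC.DZ and 3.65 and 5.21 in GC.LZ.

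The clusters held like shares of the cells of both genotypes. GC.DZ cells made up 20.8% and 20.3% of +/ki and 16.9% and 20.7% of -/ki cells (exact permutation p = 0.667), and GC.LZ cells 16.2% and 27.0% against 20.6% and 24.5%. Germinal centre cells together were 42.2 ± 7.22% and 41.3 ± 5.47%, and memory cells 34.8 ± 3.36% and 31.9 ± 0.74%. E-prePB was the cluster with the largest difference that separated the mice, at 11.2% and 13.8% against 18.6% and 15.5% (a difference of 4.52 points, exact permutation p = 0.333; edgeR on cell numbers log2 0.45, adjusted p = 0.95). With each clone counted once, among cells with a clone only, that difference was 1.27 points. A clone was recovered for 72.4% and 74.5% of E-prePB but 62.3% and 83.0% of germinal centre cells in +/ki and -/ki mice. The denominator thus changed too, and the drop cannot be credited to clone size. Plasmablasts were 3.26% and 2.94% against 2.86% and 2.80%, Mem.GC 7.55% and 11.5% against 10.6% and 10.3%, and Mem.Act 27.2% and 19.2% against 20.3% and 18.4%. Mem.Act2 held 2.36% and 1.76% against 1.57% and 2.65%. L-prePB ranged from 3.62% to 11.4% among the +/ki mice alone and was 8.71% and 5.19% in the -/ki mice. GC.LZ, E-prePB and L-prePB are compared as the authors' clusters, not as cell types. The 10 leading genes of GC.LZ held 2 dark zone markers (Aicda, S1pr2) and 1 light zone marker (Il4i1), those of E-prePB 3 marginal zone markers (Asb2, Cd1d1, Cr2), and those of L-prePB 1 macrophage marker (Adgre1), with no plasmablast marker in either pre-plasmablast cluster. Those of PB were all variable segments and held no marker, those of GC.DZ held 2 plasmablast markers beside 2 dark zone markers (Mki67 and Top2a, which are in both lists), and those of Mem.Act held 3 memory and 3 naive B cell markers. None of the 10 leading genes of any cluster passed between genotypes within it. The cells had been sorted on the reporter, so the shares are of sorted cells, not of the spleen.

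**Figure D2:**
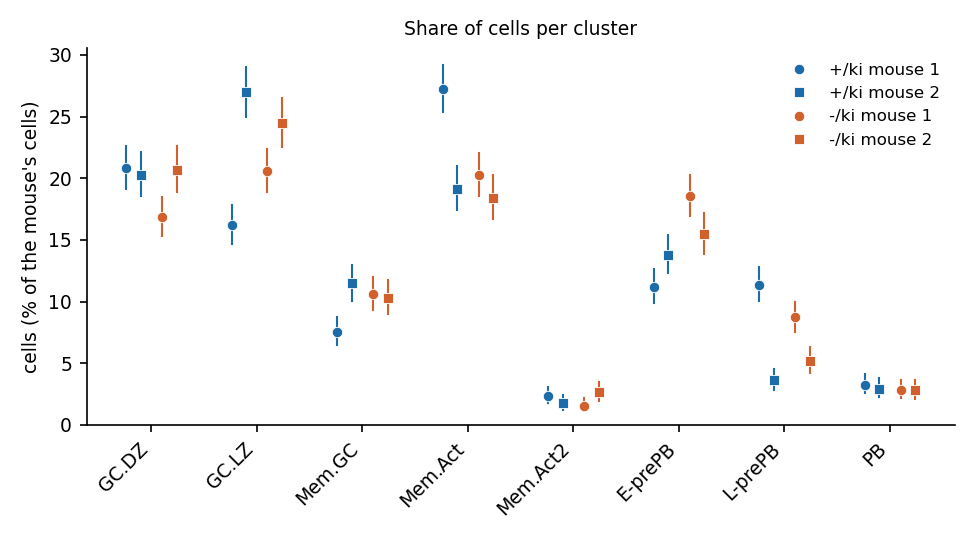
Percent of each mouse's cells in each of the authors' clusters, 1 point per mouse with a 95% exact interval. The mice of the 2 genotypes overlap in all clusters but E-prePB (11.2% and 13.8% against 18.6% and 15.5%) and PB (3.26% and 2.94% against 2.86% and 2.80%).

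Over all cells, Ighg2b, the IgG2b constant gene on chromosome 12 (113302965 to 113307933), fell from 204 ± 28.4 to 18.7 ± 1.16 CPM (edgeR log2 -3.45, standard error 0.13, adjusted p = 0.00700, n = 2 mice each). It was the only gene outside the variable segments among the 6 that passed of 11254 tested (1 higher and 5 lower in -/ki mice). No gene outside the immunoglobulin loci passed, and the genes next in order were Emp2 (log2 -2.88, adjusted p = 0.301), Oas1a, an interferon-induced antiviral gene (1.36, 0.307), Samsn1 (0.48), the Fc receptor-like Fcrl5 (0.76), Cenpv (-0.96), the transcription factor Tox (-1.02) and Lockd (0.69, all adjusted p = 0.354). Etl4 (-1.56), Hspb3 (2.90) and Irak1bp1 (-0.91) followed at adjusted p = 0.372. The other constant genes were Ighg2c (-4.99, standard error 0.91, adjusted p = 0.475), Ighg1 (-3.68), Igha (-2.41), Ighe (-1.86), Ighg3 (-1.77), Ighm (0.40, adjusted p = 0.682) and Ighd (0.21). With immunoglobulin genes left out, 5 genes passed: Fcrl5, Oas1a and Ly6k were higher, and Tox (-1.03, adjusted p = 0.0489) and Emp2 (-2.88, adjusted p = 0.0318) lower. With single mice left out this fit called 471, 254, 0 and 1 genes. At unadjusted p below 0.05 there were 835 genes where chance gives 563. Fcrl5 is a leading gene of E-prePB (229.6 CPM against 32.42 CPM in other cells), a cluster with a larger share of -/ki UMIs (log2 0.56). The difference in Fcrl5 over all cells was thus not separated from cluster shares.

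By gene group over all cells, light zone activation genes, which mark B cells that have received antigen and T cell signals, were higher in -/ki mice: 21 of 24 were positive (median log2 0.20, camera adjusted p = 1.16e-06, and adjusted p = 0.705 with an estimated correlation). Of these 24, 0 passed over all genes and 2 rose when adjusted over the list alone. Cd83 (0.41), Myc (0.38) and Ccnd2 (0.40) were examples. Myc is a leading gene of E-prePB, which held 9.32% and 11.11% of +/ki but 16.41% and 13.75% of -/ki UMIs (log2 0.56). The difference in Myc over all cells was thus not separated from cluster shares. Interferon response genes were higher for 20 of 21 (median 0.38, camera adjusted p = 5.89e-07, adjusted p = 0.705 with an estimated correlation, 0 over all genes and 1 rose adjusted over the list alone), with Ifi27l2a at 0.60, Irf7 at 0.44 and Isg15 at 0.42. All 11 MHC class II presentation genes were positive (median 0.10, adjusted p = 0.000137, adjusted p = 0.705 with an estimated correlation; H2-Eb1 0.11, H2-Ab1 0.10), as were 17 of 19 B cell receptor signalling genes (median 0.11, adjusted p = 3.39e-05, adjusted p = 0.705 with an estimated correlation; Fcgr2b 0.36, Ptpn6 0.20). No member of these 2 groups passed, over all genes or adjusted over the list alone.

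Replication and germinal centre groups were lower over all cells. All 24 S phase genes were negative (median -0.21, camera adjusted p = 3.42e-11, adjusted p = 0.705 with an estimated correlation), among them Uhrf1 (-0.33) and Dtl (-0.36). Cluster shares moved with this group: the GC.DZ cluster, led by replication genes, held 37.8% and 36.1% of +/ki but 29.7% and 34.2% of -/ki UMIs (log2 -0.21), and the S phase median was only -0.07 within GC.DZ and -0.01 within GC.LZ. Genes for the repair of AID-induced lesions were negative for all but 1 of 25 (median -0.11, adjusted p = 0.000201, adjusted p = 0.705 with an estimated correlation; Ung -0.29), and dark zone genes for all but 4 of 19 (median -0.12, adjusted p = 0.00378, adjusted p = 0.705 with an estimated correlation). Oxidative phosphorylation (3 of 27 positive, median -0.03, adjusted p = 0.00309, adjusted p = 0.705 with an estimated correlation), germinal centre identity (5 of 15 positive, median -0.16, adjusted p = 0.0137, adjusted p = 0.732 with an estimated correlation; Gcsam -0.42) and G2 and M phase (7 of 26 positive, median -0.08, adjusted p = 0.0370, adjusted p = 0.783 with an estimated correlation) were also lower. None of the members of these 6 groups passed, over all genes or adjusted over the list alone. All 6 switched Igh constant genes were negative (median -2.93, adjusted p = 4.21e-08, adjusted p = 0.705 with an estimated correlation), with 1 that fell over all genes and 6 that fell adjusted over the list alone.

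The other groups did not pass over all cells with all genes kept. The memory B cell list came closest (13 of 20 positive, median 0.17, camera adjusted p = 0.0714, adjusted p = 0.705 with an estimated correlation), with 1 that rose adjusted over the list alone. With immunoglobulin genes left out it passed at the preset correlation (camera adjusted p = 0.0355), as did erythroid and platelet markers (lower, 0.0389). Unswitched Igh constant genes were at a median of 0.31 (2 of 2 positive, adjusted p = 0.162, adjusted p = 0.705 with an estimated correlation). The plasma cell programme gave adjusted p = 0.860 (adjusted p = 0.936 with an estimated correlation; 12 of 20 positive), with a median of 0.02 while its mean and test pointed down. The unfolded protein response (19 of 30 positive, median 0.03) gave adjusted p = 0.686 and adjusted p = 0.936 with an estimated correlation. For p53 targets (8 of 16 positive, median -0.01) these were 0.432 and 0.759, for apoptosis regulators (10 of 19 positive, 0.03) 0.623 and 0.836, and for MYC and ribosome biogenesis (6 of 20 positive, -0.01) 0.666 and 0.901. Homing and adhesion receptors had a median of 0.04 and a mean of -0.07 (10 of 17 positive, adjusted p = 0.666, adjusted p = 0.836 with an estimated correlation). Immediate early genes likewise had a median of 0.04 and a mean of -0.02 (8 of 14 positive, adjusted p = 0.970, adjusted p = 0.985 with an estimated correlation). Markers of other cell types were few: T cell (4 of 8 positive, median -0.33, adjusted p = 0.127, adjusted p = 0.705 with an estimated correlation), myeloid (5 of 7 positive, median 0.25, mean -0.02; 0.679 and 0.812), NK and cytotoxic (1 of 2, -0.67; 0.658 and 0.836) and erythroid and platelet markers (0 of 2, -0.72; 0.0871 and 0.705). Adjusted over the list alone, 1 immediate early gene and 1 marker each of T, myeloid, NK and erythroid cells fell and 1 myeloid marker rose, while over all genes 0 members of these groups passed.

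In germinal centre cells 3 genes outside the variable segments passed, all lower in -/ki mice. Ighg2b fell from 137 to 8.26 CPM (log2 -4.05, standard error 0.11, adjusted p = 0.000138), Ighg2c from 40.5 to 3.38 CPM (-3.57, standard error 0.17, adjusted p = 0.00251), and Emp2, which encodes a tetraspan membrane protein, from 27.4 to 4.06 CPM (-2.75, standard error 0.23, adjusted p = 0.0340). In all 6 genes of 10382 tested passed, 2 higher and 4 lower. Emp2 did not pass with no filter on low counts (-2.76, adjusted p = 0.164) or with any 1 mouse left out (-2.99 to -2.46). Next in order and not passing were Ighm (1.03), the activation marker Cd83 (0.56) and Tox (-0.93, all adjusted p = 0.0583), Slfn2 (0.81), Etl4 (-1.69) and Zeb2 (1.21, adjusted p = 0.0612), Ighg1 (-4.36, 0.0627), and Snn (0.78), Cenpv (-0.97) and Ighd (1.11, all 0.0738). Igha did not differ in these cells, at 15.1 and 14.4 CPM. With immunoglobulin genes left out 76 genes passed, 45 higher and 31 lower in -/ki mice. Among them were the inhibitory receptor Cd72 (0.93, adjusted p = 0.00292), Bcl3 (0.83, 0.00818), Zeb2 (1.22, 0.00775) and Cd38 (0.96, 0.0492) on the higher side. Tox (-0.93, 0.00292) and the integrin Itga4 (-0.77, 0.0147) were on the lower side. Of these 76 genes DESeq2 also called 32, and with single mice left out this fit called 26, 0, 2 and 0 genes.

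By gene group in germinal centre cells, MHC class II presentation genes were higher in -/ki mice (11 of 11 positive, median 0.18, camera adjusted p = 9.35e-10, adjusted p = 0.705 with an estimated correlation). None passed over all genes and 10 rose adjusted over the list alone, such as H2-Ab1 (0.18) and H2-Eb1 (0.19). Interferon response (16 of 17 positive, median 0.46, adjusted p = 1.27e-07, 0 over all genes and 2 adjusted over the list alone; Oas1a 1.64), B cell receptor signalling (15 of 19, 0.15, adjusted p = 2.82e-05, 0 and 5; Cd72 0.92), light zone activation (19 of 24, 0.15, adjusted p = 0.000168, 0 and 1) and memory B cell genes (16 of 19, 0.26, adjusted p = 0.0137, 0 and 4 that rose, 1 that fell; Cd38 0.95) were higher too, each with adjusted p = 0.705 with an estimated correlation. S phase (1 of 24 positive, median -0.14, adjusted p = 3.11e-05; Uhrf1 -0.25), repair of AID-induced lesions (4 of 25, -0.08, adjusted p = 0.0186; Ung -0.32), MYC and ribosome biogenesis (5 of 20, -0.06, adjusted p = 0.0417; Ncl -0.15) and oxidative phosphorylation (4 of 27, -0.05, adjusted p = 0.0113) were lower, with adjusted p = 0.705 with an estimated correlation for the first 3 and 0.781 for the last. None of their members passed by either count. Switched constant genes (median -2.88, adjusted p = 4.21e-08, 2 fell over all genes and 4 adjusted over the list alone) and unswitched constant genes (median 1.07, adjusted p = 2.82e-05, 0 and 2 that rose) moved in opposite directions, both with adjusted p = 0.705 with an estimated correlation. The 2 germinal centre clusters are mixed in proportions that differ between mice, and not all groups held in each alone. In GC.LZ S phase genes were not lower (10 of 22 positive, median -0.01, adjusted p = 0.916, adjusted p = 0.955 with an estimated correlation), nor were MYC and ribosome biogenesis genes (14 of 20 positive, median 0.05, adjusted p = 0.297, adjusted p = 0.705 with an estimated correlation). Repair of AID-induced lesions passed in neither GC.DZ (adjusted p = 0.1605) nor GC.LZ (adjusted p = 0.2425). In GC.LZ memory B cell genes (adjusted p = 0.142) and oxidative phosphorylation (adjusted p = 0.149) did not pass either, and in GC.DZ light zone activation did not (adjusted p = 0.134).

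Cells of the GC.LZ cluster were also fitted alone, a choice made after the authors' cluster names were seen. The activation marker Cd83 (chromosome 13) rose from 357 to 563 CPM (log2 0.66, standard error 0.06, adjusted p = 0.0110) and the NF-kappaB cofactor Bcl3 (chromosome 7) from 39.4 to 81.8 CPM (1.05, 0.11, 0.0202). Cd72 rose from 249 to 478 CPM (0.95, 0.10, 0.0202), and Slfn2, linked to lymphocyte quiescence, from 92.5 to 168 CPM (0.86, 0.10, 0.0202). Ighm rose by 1.09 (standard error 0.06, adjusted p = 0.000817). Emp2 (chromosome 16) fell from 28.4 to 3.19 CPM (-3.14, 0.27, 0.00730) and Crip1, a LIM-domain gene, from 1901 to 1366 CPM (-0.48, 0.05, 0.0110), beside Ighg2b (-4.54), Ighg1 (-4.32) and Ighg2c (-4.24). Here 20 genes of 9100 passed, 13 higher and 7 lower, and 67 passed with immunoglobulin genes left out (38 and 29), of which DESeq2 also called 11. Light zone activation genes were higher (19 of 23 positive, median 0.30, camera adjusted p = 4.53e-07, adjusted p = 0.705 with an estimated correlation, 1 rose over all genes and 5 adjusted over the list alone), as were MHC class II genes (11 of 11, median 0.21, adjusted p = 1.76e-09, adjusted p = 0.705 with an estimated correlation, 0 and 9). Among cells with an unswitched call only, a choice added after the data were seen, none of the 7 of these genes that were tested passed: Ighg2b was at -1.76, Bcl3 0.41, Cd83 0.22, Slfn2 0.15, Cd72 0.10, Ighm 0.04 and Crip1 0.00.

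In GC.DZ cells Ighg2b (log2 -3.77, adjusted p = 7.46e-05) and Ighg2c (-3.24, adjusted p = 0.0219) fell, and 5 genes of 9773 passed, 3 higher and 2 lower. With immunoglobulin genes left out 42 passed, 24 higher and 18 lower, of which DESeq2 also called 13. Interferon response genes were higher for 17 of 17 (median 0.84, camera adjusted p = 9.57e-10, adjusted p = 0.705 with an estimated correlation, 0 over all genes and 7 adjusted over the list alone). Oas1a (2.06), Irf7 (0.80) and Ifi27l2a (0.84) were examples. G2 and M phase genes were higher for 23 of 26 (median 0.10, adjusted p = 4.06e-05, adjusted p = 0.705 with an estimated correlation, 0 and 3; Cenpf 0.41, Mki67 0.20), while S phase genes were lower (2 of 24 positive, median -0.07, adjusted p = 0.000377, adjusted p = 0.705 with an estimated correlation). T cell markers were lower in -/ki GC.DZ cells (6 measured, median -1.79, adjusted p = 0.000980, adjusted p = 0.705 with an estimated correlation, 0 and 3 that fell). Cd3e, for example, read 3.14 CPM in +/ki and 0.222 CPM in -/ki cells.

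In memory cells Ly6k, a gene for a GPI-anchored surface protein on chromosome 15, rose in -/ki mice from 8.44 to 42.6 CPM (log2 2.33, standard error 0.19, adjusted p = 0.00265, n = 2 mice each). The chaperone genes Ahsa2 (30.8 to 58.8 CPM, log2 0.93, 0.13, 0.0354) and Hsph1 (55.0 to 95.6 CPM, log2 0.80, 0.11, 0.0354) also rose, as did Ighm (888 to 1271 CPM, log2 0.52, 0.06, 0.0107). Ighg1 fell from 48.9 to 1.71 CPM (-4.82, 0.64, 0.0294), Ighg2b from 97.1 to 15.9 CPM (-2.61, 0.27, 0.00976) and Ighg2c from 17.1 to 3.23 CPM (-2.35, 0.33, 0.0378). In all 16 genes of 9128 passed, 10 higher and 6 lower, and 4 passed with immunoglobulin genes left out (3 higher and 1 lower; 46, 132, 2 and 3 with single mice left out). Ly6k passed under every alternative, while Ahsa2 and Hsph1 did not pass when thinned, in DESeq2 or without either -/ki mouse. Interferon response genes were higher (17 of 21 positive, median 0.29, camera adjusted p = 0.00296, adjusted p = 0.705 with an estimated correlation, 0 over all genes and 1 adjusted over the list alone), with Oas1a at 1.19. Mem.Act2, led by interferon-induced genes, held 1.18% and 1.14% of all +/ki UMIs and 1.06% and 1.83% of -/ki ones. With immunoglobulin genes left out the group passed in Mem.GC (camera adjusted p = 0.00180), but not in Mem.Act (0.0614) or Mem.Act2 (0.866). Immediate early genes were lower (3 of 12 positive, median -0.07, adjusted p = 0.0138, adjusted p = 0.705 with an estimated correlation, 0 and 1 that fell), with Dusp1 at -1.33 (adjusted p = 0.216). Switched constant genes were lower (median -2.35, adjusted p = 4.21e-08, 3 fell over all genes and 4 adjusted over the list alone), and unswitched ones higher (median 0.24, 1 of 2 positive, adjusted p = 0.0137, 1 and 1 that rose), both with adjusted p = 0.705 with an estimated correlation.

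Ly6k rose in 2 memory clusters fitted alone and in early pre-plasmablasts. It went from 15.5 to 56.0 CPM in Mem.GC (log2 1.83, adjusted p = 0.00546), from 4.47 to 34.2 CPM in Mem.Act (2.86, 0.00246) and from 16.2 to 73.4 CPM in E-prePB (2.17, 0.00819), where it was the only gene that passed of 8271. In Mem.GC the actin-bundling gene Fscn1 fell from 83.6 to 26.4 CPM (-1.67, 0.00730), with Slpi (-2.09, 0.0428), Fcer1g (-3.45, 0.0493), Gimap7 (-0.60, 0.0480), Tmsb10 (-0.31, 0.0429) and Igha (-1.70, 0.0127). Fcer1g leads the L-prePB cluster, so its fall in Mem.GC stands beside a gene of another cluster. In Mem.Act Hsph1 rose (0.90, 0.0132), while the RNA-binding protein gene Zfp36l2 (238 to 124 CPM, log2 -0.96, 0.0252) and the glucocorticoid-induced Tsc22d3 (717 to 472 CPM, log2 -0.61, 0.0124) fell. Mem.GC had 23 passing genes (10 higher and 13 lower; 65 with immunoglobulin genes left out, 28 and 37) and Mem.Act 13 (8 and 5; 26, 19 and 7). DESeq2 also called 4 of these 65 and 4 of these 26. With 1 cell per clone none of the named genes of Mem.GC outside the immunoglobulin loci passed, Ly6k among them (1.51, adjusted p = 0.120), and when thinned none of those of Mem.Act did (Ly6k 2.84, adjusted p = 0.119). Mem.Act2 had 0 in edgeR, with 86 at unadjusted p below 0.05 where chance gives 115, and 2 in DESeq2.

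**Figure D3:**
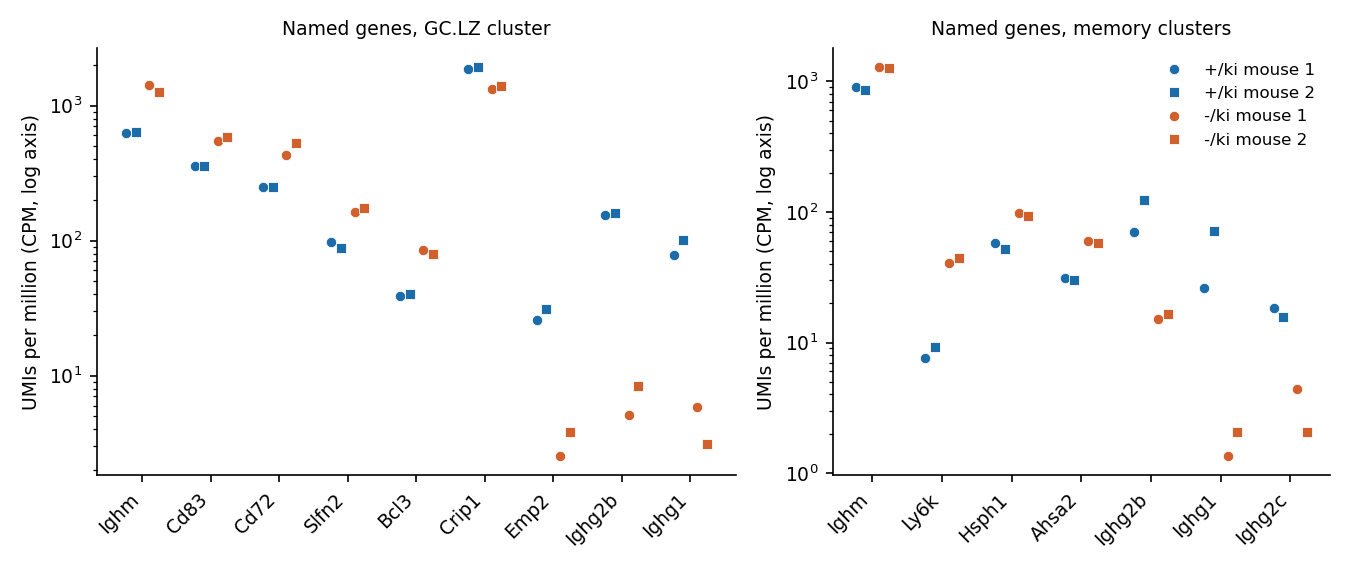
Expression in CPM (log axis) of named genes in the GC.LZ cluster (left) and in the memory clusters together (right), 1 point per mouse, with +/ki mice in blue and -/ki mice in orange. Cd83 lies at 357 CPM in +/ki and 563 CPM in -/ki GC.LZ cells, and Ly6k at 8.44 and 42.6 CPM in memory cells.

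In plasmablasts Ighg2b fell from 1272 to 27.7 CPM (log2 -5.51, standard error 0.37, adjusted p = 0.0314, n = 2 mice each), the only gene outside the variable segments among the 5 that passed of 4764 tested (2 higher and 3 lower). Not passing were the replication-dependent histone Hist1h2ap (-2.84, adjusted p = 0.0821), Ighg2c (0.257), the survival gene Bcl2 (1.31, 0.314), Pclaf (-2.18, 0.377), and Ccna2, Igha, Hist1h2ae, Slc25a19, Selenop and Pycard (all 0.774). Ighg2c went from 3712 and 592 CPM in the +/ki mice to 1.82 and 2.47 CPM in the -/ki mice. DESeq2, run on all genes, did not call Hist1h2ap, and with pre-plasmablasts added to the class it was at -0.38. With immunoglobulin genes left out only Hist1h2ap passed in edgeR (-2.83, adjusted p = 0.0322). With single mice left out that fit called 98, 92, 22 and 26 genes. Ighg2b itself did not pass when cells were thinned, with 1 cell per clone or without either -/ki mouse (-5.74 to -5.07). S phase genes were lower in -/ki plasmablasts (1 of 13 positive, median -0.57, camera adjusted p = 0.000232, adjusted p = 0.705 with an estimated correlation), with Rrm2 at -1.54 and Mcm6 at -0.52. G2 and M phase (0 of 5 positive, median -0.49, adjusted p = 0.0325, adjusted p = 0.705 with an estimated correlation, 1 fell adjusted over the list alone) and homing receptor genes (1 of 11 positive, median -0.26, adjusted p = 0.0167, adjusted p = 0.705 with an estimated correlation; Itgb7 -1.59, Klf2 -1.77) were lower too. No S phase or homing gene passed by either count. The plasma cell programme itself did not differ (11 of 20 positive, median 0.02, mean -0.04, adjusted p = 0.753, adjusted p = 0.900 with an estimated correlation; Sdc1 -0.31). Switched constant genes were lower (0 of 5 positive, median -5.42, adjusted p = 0.000228, adjusted p = 0.705 with an estimated correlation, 1 fell over all genes and 4 adjusted over the list alone).

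Late pre-plasmablasts had 5 passing genes of 7152, all variable segments and all higher in -/ki mice. The interferon-induced Ifi27l2a went from 829 to 1634 CPM in them (log2 0.98, adjusted p = 0.119, not passing), and passed with immunoglobulin genes left out (0.97). Interferon response genes were higher for 12 of 12 (camera adjusted p = 1.21e-06, adjusted p = 0.705 with an estimated correlation, 0 over all genes and 1 adjusted over the list alone).

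The genotype effect differed between plasmablasts and germinal centre cells for 9 genes of 10091 tested in edgeR with the mouse as a block. Of these, 8 were immunoglobulin variable segments, whose link to single clones was not tested, and the other was Hist1h2ap. On the common scale of this joint fit, which is not that of the single class fits, Hist1h2ap read 65.7 and 63.1 CPM in +/ki and 8.48 and 9.53 CPM in -/ki plasmablasts. In germinal centre cells it read 325 and 288 against 289 and 356 CPM (difference of log2 fold changes -2.90, standard error 0.28, adjusted p = 0.0401). On simulated data this test made 10 false calls, while it recovered 2 of 100 genes changed by a fold of 2. Of 100 genes changed by a fold of 4 it recovered 51.

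Expanded clones, those of 2 or more cells, were found in every mouse. The +/ki mice had 1164 and 815 clones and the -/ki mice 1137 and 971, over 1436, 1241, 1698 and 1480 cells with a clone. Expanded clones held 27.5% and 45.3% of these cells in +/ki and 45.7% and 46.2% in -/ki mice (exact permutation p = 0.333). With each mouse drawn down to 1241 cells the mice overlapped, at 26.0% and 45.3% against 41.3% and 43.9% (exact permutation p = 1), as they did with clones of 3 or more cells (exact permutation p = 0.667). Clones with both germinal centre cells and plasmablasts were 6.504% and 2.94% of expanded clones in +/ki mice (8 of 123 and 4 of 136) and 4.19% and 2.87% in -/ki mice (9 of 215 and 5 of 174). With pre-plasmablasts counted too, a choice added after the data were seen, 14.6% and 11.8% against 20% and 13.2% of expanded clones held germinal centre cells and cells of PB, E-prePB or L-prePB. The largest clone held 21, 31, 37 and 28 cells in the 4 mice. A clone was recovered for fewer +/ki than -/ki germinal centre cells (62.3 ± 3.24% and 83.0 ± 2.46%), so numbers of clones and of clonal links are lower limits that differ between genotypes. Drawing each mouse down to 1241 cells turned the difference in number of clones from 64.5 to -58.8.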

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

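The genotype effect differed between plasmablasts and germinal centre cells for 9 genes, a difference between groups found with the test planned for it. Of these, 8 were immunoglobulin variable segments, whose link to expanded clones was not tested. On simulated data with 100 genes changed by each fold this test made 10 false calls. In the data it called 6 genes with no mouse block. The remaining gene, Hist1h2ap, had a difference of log2 fold changes of -2.90. Hist1h2ap, like Pclaf and Ccna2, is among the leading genes of the GC.DZ cluster. No explanation was tested for it. No mouse was tested for lying far from the others, and the effect of leaving out each mouse is given with the alternatives.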

How the results depend on the processing

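Class switching, V mutations and the loss of Ighg2b kept their direction under every alternative. The difference in switched cells (-21.3 points) was -22.05, -19.77 and -15.45 points by the UMI rules and ran from -25.68 to -16.84 points with each mouse left out. The difference in V mutations ran from -3.069 to -2.069. Of 41 passing pairs of gene and class named in the text, none reversed. RLE size factors kept 39 of 41 past the threshold, no filter 40, robust empirical Bayes 39, cells above 3 times the median left out 38, DESeq2 31, 1 cell per clone 31, thinning 23 of 38, and leaving out immunoglobulin genes 21 of 21. In GC.LZ cells with an unswitched call 0 of 7 still passed. With each mouse left out 23 to 37 of 41 still passed. The 68 pairs named as not passing stayed so in 670 comparisons, passed in 124 and reversed in 7. In that case the lone mouse is assumed to vary like the others. No paired analysis was possible because mice of different genotype share only a number.

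The number of changed genes depended on the processing far more, and where nothing else is said the cause was not tested. RLE size factors kept all 12 counts within 1.5 times. With no filter on low counts the numbers were 11 over all cells (6 as reported), 3 in germinal centre cells (6), 170 in plasmablasts (5), 164 in memory cells (16), 46 in GC.DZ (5), 264 in GC.LZ (20), 174 in Mem.GC (23), 112 in Mem.Act (13), 60 in Mem.Act2 (0), 129 in E-prePB (1), 136 in L-prePB (5) and 22 in the interaction (9). Leaving out immunoglobulin genes gave 76 in germinal centre cells, 1 in plasmablasts, 4 in memory cells, 42 in GC.DZ, 67 in GC.LZ, 65 in Mem.GC, 26 in Mem.Act, 1 in Mem.Act2, 2 in E-prePB and 1 in L-prePB. The prior degrees of freedom rose with it, from 4.35 to 9.89 in germinal centre cells, 9.88 to 37.67 in Mem.Act and 9.01 to 1995.95 in Mem.GC. In Mem.GC the spread of a single gene between mice thus hardly counted. The fit with immunoglobulin genes left out shared 13 of its 42 GC.DZ and 11 of its 67 GC.LZ calls with DESeq2 run on all genes. It also shared 4 of its 65 Mem.GC and 4 of its 26 Mem.Act calls. With each mouse left out it called 274, 118, 1 and 0 genes in GC.DZ, 242, 201, 17 and 15 in GC.LZ, 50, 36, 17 and 17 in Mem.GC, and 21, 82, 1 and 4 in Mem.Act. DESeq2 gave 41 over all cells, 55 in germinal centre cells, 39 in plasmablasts, 32 in GC.DZ, 2 in Mem.Act2, 5 in E-prePB and 12 in L-prePB. Thinned cells gave 14 in germinal centre cells, 0 in plasmablasts, 6 in memory cells, 12 in GC.DZ, 13 in Mem.GC, 0 in Mem.Act, 9 in E-prePB and 3 in L-prePB. Leaving out cells above 3 times the median gave 17 in GC.DZ and 7 in E-prePB.

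Among alternatives added after the data were seen, 1 cell per clone gave 13 over all cells, 29 in germinal centre cells, 3 in plasmablasts, 32 in GC.LZ, 7 in Mem.GC, 5 in E-prePB and 8 in L-prePB. Robust empirical Bayes gave 65 in germinal centre cells, 2 in plasmablasts, 33 in GC.DZ, 54 in GC.LZ, 54 in Mem.GC, 32 in Mem.Act, 4 in Mem.Act2, 16 in E-prePB and 9 in L-prePB. Cells with an unswitched call only gave 4 in GC.LZ. With each mouse left out the numbers ran from 6 to 62 over all cells, 0 to 14 in germinal centre cells, 0 to 34 in plasmablasts, 10 to 239 in memory cells, 16 to 146 in GC.DZ, 27 to 134 in GC.LZ, 21 to 151 in Mem.GC, 3 to 30 in Mem.Act, 3 to 49 in Mem.Act2, 8 to 68 in E-prePB and 0 to 211 in L-prePB.

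Of the 66 pairs of list and class called by camera, 0 were called with an estimated correlation and 0 by fry, while 51 to 82 were called with each mouse left out. The estimated correlation has only 2 mice per genotype to rest on. With immunoglobulin genes left out, an alternative added for the lists, camera called 67 pairs at the preset correlation.

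Shares of clusters moved with single mice. The difference ran from -3.697 to 0.1322 points in GC.DZ, -4.419 to 6.309 in GC.LZ, -1.011 to 2.905 in Mem.GC, -7.89 to 0.1767 in Mem.Act, -0.4918 to 0.5876 in Mem.Act2, -4.428 to 3.33 in L-prePB and -5.946 to 4.271 for germinal centre cells together. E-prePB kept its sign (2.962 to 6.075), as did plasmablasts (-0.4262 to -0.1142). Counting each clone once per cluster used only cells with a clone and reversed the germinal centre difference to 3.061 points. A clone was recovered for 62.3% of +/ki but 83.0% of -/ki germinal centre cells, so the reversal cannot be credited to clone size. Taking only B lineage clusters as denominator changes nothing, since all clusters are of the B lineage. The difference in number of clones ran from -110 to 239 and reversed to -58.8 with each mouse drawn down, which takes out the larger number of -/ki cells with a clone. The difference in clones joining germinal centre cells and plasmablasts ran from -2.974 to 0.5886 points, and with pre-plasmablasts counted too from 0.019 to 6.801 points. Aicda ran from -13.53 to 21.51 CPM over all cells, in log2 terms from -0.10 to 0.21, and was -0.09 with 1 cell per clone. In germinal centre cells Igha was 0.08 when thinned and ran from -0.37 to 0.18 with each mouse left out. In plasma cells Ighm was -0.06 with pre-plasmablasts added.

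Mem.Act2 (157299 to 243178 UMIs per mouse), L-prePB (468327 to 1493846) and plasmablasts (881105 to 1165308) were among the shallowest fits. Recovery of genes changed by a fold of 2 on simulated data was lowest in the interaction (2%), L-prePB (5%) and plasmablasts (16%). It rose to 65% in L-prePB and 56% in plasmablasts with immunoglobulin genes left out, so depth alone did not set it.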

Other observations

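In early pre-plasmablasts the genes for light zone activation were higher in -/ki mice (camera adjusted p = 0.00808, adjusted p = 0.705 with an estimated correlation), and MHC class II genes lower (1 of 11 positive, adjusted p = 0.00808, adjusted p = 0.705 with an estimated correlation). In Mem.GC cells MHC class II genes were also lower (1 of 11 positive, median -0.08, adjusted p = 0.00976, adjusted p = 0.705 with an estimated correlation), opposite to germinal centre cells. The edgeR fit without immunoglobulin genes called 65 Mem.GC and 26 Mem.Act genes. DESeq2, run on all genes, also called only 4 and 4 of these. In that edgeR fit the chemokine receptor Cxcr3 (-1.20) and Jchain (-0.83) were lower and Bhlhe40 (2.22) higher in -/ki Mem.GC cells. Slamf1 (1.12) and Cd38 (0.40) were higher and Ccr7 (-0.52) lower in -/ki Mem.Act cells. In Mem.GC its prior degrees of freedom were 1995.95, so the spread of a single gene between mice hardly counted.

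Plasmablasts shared clones with pre-plasmablasts in 25% and 24.1% of +/ki and 45.2% and 36.7% of -/ki plasmablasts with a clone. They shared clones with germinal centre cells in 23.4% and 25.9% against 24.2% and 10.2%. These are shares of cells, so 1 clone can count many times. E-prePB and PB shared 3 and 2 clones in +/ki and 8 and 7 in -/ki mice. Their ratios to shuffled class labels were 0.62 and 0.26 against 0.64 and 0.81. For L-prePB and PB the clones were 7 and 5 against 6 and 3, and the ratios overlapped (0.55 and 0.78 against 0.67 and 0.50). GC.LZ and early pre-plasmablast cells shared 6 and 10 clones in +/ki and 7 and 2 clones in -/ki mice, counts that overlap. Shuffled class labels gave 10.3 and 20.1 against 49.7 and 32.7. The ratios to shuffled labels, 0.580 and 0.498 against 0.141 and 0.0613, did not overlap. GC.LZ and late pre-plasmablast cells shared 3 and 1 against 18 and 9 clones, where shuffled labels gave 28.5 and 16.5 against 32.5 and 21.4.

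Technical and biological causes were weighed for 3 patterns. All tests were chosen after the pattern was seen, and for the third the predictions on recovery and on V mutations were written only after their results.

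A clone was recovered for 64.6% and 60.0% of +/ki germinal centre cells against 84.7% and 81.3% of -/ki ones. With cells matched on total UMIs the gap was 21.02 points (18.25 to 24.01 over 4 pairs of mice), so depth did not account for it. Matched on the summed UMIs of heavy and light chain constant genes it was 20.24 points (17.22 to 23.8), so this sum did not either. Heavy chain RNA was not matched alone. Of +/ki germinal centre cells, 537 of 785 and 612 of 915 held at least 5 Igh constant UMIs. In -/ki mice 704 of 813 and 693 of 854 did, so less heavy chain RNA is not excluded. Among cells unswitched by UMIs, all with at least 5 Igh constant UMIs, the gap was 6.734 points (3.375 to 10.09), between the 2 predictions. Switched +/ki cells had a clone in only 58.5% and 57.0%, so switched chains may account for part of the gap. Mutated V regions, a biological cause, were not tested.

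The 67 genes called in -/ki GC.LZ cells with immunoglobulin genes left out may reflect switched cells, which were 34.4% of +/ki and 0.143% of -/ki GC.LZ cells with a call. In cells with an unswitched call a median of 40.91% of the log2 fold change was kept (quartiles 25.49 to 63.79), with 58 of 65 genes in the same direction. Another measure was added afterwards, the difference in log2 of CPM plus 5 over all 67 genes. By it cells unswitched by UMIs kept a median of 67.76% and cells with any call 80.06%. Random subsets with as many cells as had an unswitched call kept 99.09%. The 40.91% comes from an edgeR refit over 65 genes, so it cannot be set directly beside these values. For memory cells placed in the GC.LZ cluster, 77.61% of the 67 genes (65.78 to 86.89) moved in the direction of Mem.GC, where at least 90% had been predicted. Both differences subtract the same +/ki GC.LZ values, which favours agreement, and the interval takes genes as independent. No share over all genes was computed. The test thus leaves this cause open for the genes that moved with Mem.GC, and the cause does not account for the others. In +/ki mice Cd83 (-1.22) and Cd72 (-1.10) were lower in Mem.GC than in GC.LZ, against this cause, while Klf2 (5.70), Cd38 (2.30), Slfn2 (1.498), Bcl3 (0.55), H2-Aa (0.39) and Emp2 (-4.30) went with it, and altered selection without AID was not tested.

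Late pre-plasmablast clones with a germinal centre member were 5.41% and 4.17% in +/ki mice (8 of 148 and 2 of 48) against 20.3% and 25.4% in -/ki mice (29 of 143 and 17 of 67; exact permutation p = 0.333). This pair was picked from 17 pairs of clusters examined, and L-prePB is led by Fcer1g and the macrophage marker Adgre1. A lower number of recovered germinal centre cells did not account for this, as both -/ki mice stayed above in 100% of draws to the same number. The draws were random, so they cannot exclude that particular +/ki clones were lost. A few large clones did not account for the pattern either (a gap of 13.89 points without clones of over 5 cells). V mutations splitting +/ki clones are not excluded: GC.DZ clones with a GC.LZ member were 16.5% and 40.8% in +/ki and 35% and 27.7% in -/ki mice, an overlap of 13.09 points that rests on 1 +/ki mouse, while early pre-plasmablast clones did not follow (5.19% and 3.71%). Biological causes were not tested.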
